A study of Drosophila melanogaster with 4 samples.

How the data were processed

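The series measured binding of Suppressor of Hairless, Su(H), in the Drosophila melanogaster cell line Kc167 by chromatin immunoprecipitation and sequencing (ChIP-seq). Su(H) is the DNA-binding transcription factor of the Notch pathway and the fly counterpart of mammalian RBPJ. Kc167 is an established line derived from embryos and is female according to the labels. The labels give 3 ChIP libraries, numbered as replicates, and 1 input DNA library, which is sheared chromatin without immunoprecipitation. Cells were fixed with 1.8% formaldehyde for 15 minutes per the labels' protocols, and the antibody was a rabbit polyclonal raised against residues 259 to 594 of Su(H).

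The values analysed here come from 1 deposited list of peaks for the whole series. Per the file headers it uses FlyBase release 5 coordinates, and its source column names MACS as the caller. The submitters' processing notes list CASAVA 1.7.0.2 and 1.7.0.3, BWA, MACS2 and the build BDGP5, without saying how each was used. The authors deposited for each peak a start, an end and 1 score, with no summit, fold enrichment or read count. The calling threshold, the number of mapped reads and which ChIP libraries entered the list are not given in the sources used here. The list holds no value per library, so no replicate error could be attached to any peak, and the depth of each library is unknown. Intervals of shares, counts and ratios of shares are exact, and those of odds ratios use a normal approximation on the log scale. Both cover counting error over peaks only.

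The scale of the deposited score is not stated, so it was worked out from the values. In its usual form MACS compares the pileup of ChIP fragments at a position with a Poisson background. That background is the larger of a genome-wide level and the local level in the input. If many peaks share 1 background, their scores must repeat at the values that successive whole counts give. Scores shared by at least 25 peaks and under 40 were compared with −log10 of the Poisson upper tail, for background means from 10 to 500. The mean that placed most of them within 0.015 of such a value was then refined on all peaks. A peak was called on the ladder where its score lay within 0.0075 of a value for a whole count. For each peak, the count that would give its score against this background, divided by the background, was taken as its fold over background. This fold is an upper bound where a higher local background was used, because a higher background needs a smaller fold to reach a given score. The bound assumes that no peak was scored against a lower background. With 3 sets of 14384 simulated scores of known background, the fit erred by at most 0.007. It recovered at least 99.88% of the simulated scores on the ladder and put 3.67% to 9.84% of the others on it by chance.

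Peaks on the 6 assembled arms (2L, 2R, 3L, 3R, 4 and X) entered the tests. No release 5 genome was used here, so the length of each arm was taken as the end of its last peak. The share of peaks on each arm was compared with its share of length by a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 6 arms. Clustering was tested by the median distance between neighbouring peak midpoints against 1000 random placements on the same arms, two-sided, for which 0.002 is the smallest p possible. In 20 simulated uniform placements of 13913 peaks, clustering was called in 0 and an arm in 1. Weak peaks are the 50% with the lowest scores and strong peaks the 10% with the highest. Peaks were counted in bins of 1 Mb and 100 kb. Comparisons of 1 Mb bins left out arm 4 and the incomplete last bin of each long arm. The share of strong peaks on each arm was compared with 10000 exchanges of whole windows of 100 kb or 1 Mb among the arms, two-sided, with Benjamini-Hochberg adjustment over the 6 arms. Windows without a peak were left out, and each window kept its peaks.

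The tests of peaks per arm and of clustering, with the alternatives that kept only higher scores or merged peaks, were fixed before the data were examined. The score ladder, the classes of weak and strong peaks with their tests, the counts in bins and the placement within bins were added after. The alternatives fixed in advance kept only the upper 50% of the score, or merged peaks less than 1 kb apart. Of the planned analyses, 3 were run, including a description of the peaks without a test, and 6 were not. The tests not run were those of start sites, of 16 sequence motifs and of 17 gene lists, together with scores by distance to start sites. They need a genome and annotation of release 5. The gene table at hand is of assembly release 6 and was not used, and coordinates were not converted between releases. By the rule set for that case, the 10 highest-scoring peaks on the assembled arms are named, by position. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.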

Results

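ChIP-seq of Su(H) in Kc167 cells comprised 3 ChIP libraries and 1 input library, from which the authors deposited 1 list of 14384 peaks. Of these, 13913 lay on the 6 assembled chromosome arms and 471 on unplaced or heterochromatic scaffolds. The peaks covered 11012 kb in all. The list carries no value per library, so no comparison below has a replicate check, and tests measure only how peaks are spread within this list. Positions are in FlyBase release 5, and the genes at these positions were not analysed here.

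The first question was how far the Su(H) peaks stood above the background of their score. Most stood little above it, and a small set was high and wide. Enrichment over local input may exceed the fold over background where the input lay below the genome-wide level. Many peaks lay close together, and merging those under 1 kb apart left 6539. Whether such neighbours are parts of the same site was not tested. The median fold over background was at most 1.65, and 3070 peaks (21.3%) could reach 2-fold. Only 815 peaks could reach 4-fold, and the highest value was 10.4-fold. The median score was 16.1, with 25% of peaks under 11.8 and 25% above 28.2. Scores ran from 5.66 to 1270.81.

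These folds rest on the scale of the score, which the values themselves gave. All 92 of the scores shared by at least 25 peaks and under 40 lay within 0.015 of the ladder of −log10 Poisson p-values against a background mean of 195.9. The steps of this ladder widened from 0.16 near a score of 8 to 0.24 near a score of 20. Of all peaks, 9724 (67.6%, exact 95% interval 66.8% to 68.4%) lay on the ladder. With 48 other background means within 6 of the fitted one, between 1.77% and 18.3% of peaks did. The score therefore had the values of an unadjusted −log10 p-value. The other 4660 peaks lay off the ladder, and their folds are upper bounds.

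**Figure D1:**
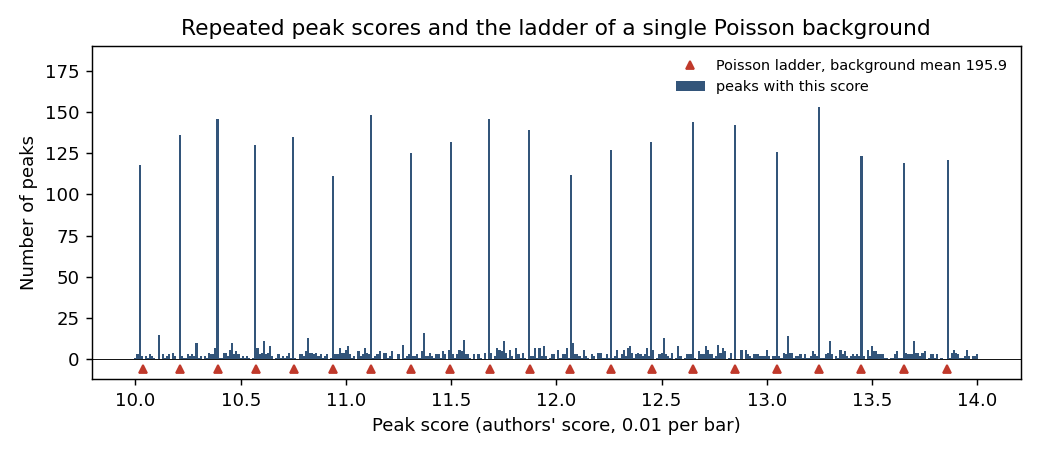
Number of peaks at each score between 10 and 14 (bars, 0.01 score units wide) and the scores that successive whole counts give against a Poisson background with a mean of 195.9 (triangles). The tall bars stand at the triangles, and the scores between them are held by few peaks each.

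Strong peaks were wider than weak ones. The 1439 strong peaks (score 106.8 or above) had a median width of 2124 bp, against 311 bp for the 7192 weak peaks (score 16.1 or below). Strong peaks made up 33.3% of the covered sequence and weak peaks 24.2%. The median fold over background was at most 4.22 in strong and at most 1.54 in weak peaks. Across peaks, score and width were correlated (Pearson's r = 0.73, Spearman's rho = 0.73, permutation p = 0.0001, the smallest that 10000 permutations allow). Peaks of 1 list are not independent replicates, and a caller extends a higher peak further. Peaks of 5 kb or more numbered 125, and 118 of them were strong.

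The highest-scoring peak on the arms lay on 3R from 27536815 to 27542203, with a score of 1270.81 and a fold over background of 10.4. It was followed by 2R from 8901655 to 8903997 (score 1046.77, 9.23-fold). The next were a pair on 2L, from 14489199 to 14492309 (1004.54, 9.0-fold) and from 14408200 to 14411495 (950.53, 8.71-fold). The peaks on 3R from 5374432 to 5378039 and on 2R from 15993266 to 15995639 had the same score of 889.03 and a fold of 8.38. The remaining 4 were on 3L from 1586003 to 1588758 (888.11), on 2L from 13510871 to 13515762 (877.05), on 2R from 3947213 to 3953605 (855.97) and on X from 19046657 to 19050710 (855.06). All 10 lay on the ladder and were 2343 to 6393 bp wide.

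The widest enriched regions were other ones. The widest peak covered 22944 bp of X, from 7582038 to 7604981, with a score of 664.37. A second on X, from 2184736 to 2202881, was 18146 bp wide. On 2L, a peak of 14124 bp (513717 to 527840) lay close to one of 12212 bp (543923 to 556134). All 4 of these peaks lay off the ladder, so their folds of 4.70 to 7.25 are upper bounds. The window of 2L from 500001 to 600000, which holds both, had the largest covered length of all 1204 windows of 100 kb, with 63.2 kb in 40 peaks, of which 39 were off the ladder. Next came 3R from 12000001 to 12100000 (59.6 kb in 44 peaks) and 3R from 17400001 to 17500000 (55.7 kb in 39 peaks, 10 of them strong). The median window held 7 peaks, and 156 windows (13.0%) held 0.

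The next question was how the called peaks were divided among the chromosome arms. Arm 2R was the richest in peaks, and in the list as deposited 3L and then 2L were the poorest of the long arms. Peaks were unevenly spread along 2L and 3L, and long peak-poor stretches of both are described below. After peaks under 1 kb apart were merged, 2L had fewer than 3L (40.4 against 41.9 per Mb). With the upper 50% of scores 3L stayed the poorest (47.4 per Mb), and X (54.2) and 2L (54.9) were close to each other. On 2R there were 154 peaks per Mb (exact 95% interval 149 to 159), 1.33 times its share by length (adjusted exact binomial p = 9.8e-67). On 3R there were 129 per Mb (125 to 134), a ratio of 1.12 (adjusted exact binomial p = 1.0e-13). Arm 2L had 98.7 per Mb (94.7 to 103), a ratio of 0.85 (adjusted exact binomial p = 1.4e-17), and 3L had 89.0 per Mb (85.3 to 92.8), a ratio of 0.77 (adjusted exact binomial p = 1.5e-45). The small arm 4 had 75.9 per Mb (61.6 to 92.5), a ratio of 0.66 (adjusted exact binomial p = 1.0e-05). The X had 112 per Mb (108 to 116), a ratio of 0.97 that missed the threshold (adjusted exact binomial p = 0.057). Because peaks lie in groups, these p-values are too small. Among the long arms the share of peaks off the ladder ran from 23.1% on 3R to 54.0% on 2L, so the local background may differ between arms. Counts of called peaks cannot separate such a difference from one in binding. With peaks under 1 kb apart merged, the ratio of arm 4 was 1.04 (adjusted exact binomial p = 0.91), and with the upper 50% of scores that of 3R was 0.99 (adjusted exact binomial p = 0.81) and that of 2L was 0.97 (adjusted exact binomial p = 0.34).

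The comparisons of strong peaks were added after the data were seen. Among strong peaks the ratio to the share by length spanned 0.82 to 1.15 over the 5 long arms, against 0.77 to 1.33 for all peaks. There were 13.1 strong peaks per Mb on 2R, 12.7 on X, 11.8 on 3R, 10.4 on 3L and 9.32 on 2L. Arm 4 had 4 strong peaks, or 3.10 per Mb (exact 95% interval 0.844 to 7.93). By share, 11.6% of the peaks of 3L and 11.4% of those of X were strong, against 8.47% on 2R. Because peaks lie in groups, these shares were tested by exchanging whole windows among the arms. With windows of 100 kb, 3L, X and 2R passed (two-sided permutation, adjusted p = 0.020, 0.042 and 0.046 over the 6 arms), as did arm 4 with 4.08% (adjusted p = 0.020), and 2L (9.44%) and 3R (9.12%) did not. With windows of 1 Mb no arm passed (lowest adjusted permutation p = 0.17), so these differences are not established beyond the variation along the arms.

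**Figure D2:**
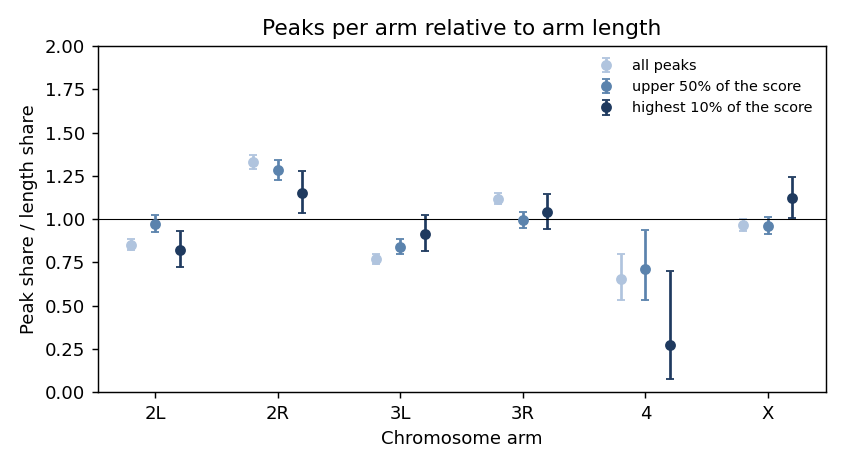
Share of peaks on each chromosome arm divided by the arm's share of total length (points) with exact 95% binomial intervals (bars), for all peaks, the upper 50% and the highest 10% of scores. For all peaks 2R stands highest at 1.33 and arm 4 lowest at 0.66, and for the highest 10% the 5 long arms lie between 0.82 and 1.15.

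Peaks lay in groups along the arms. The median distance between neighbouring midpoints was 1666.5 bp, against 5836 bp (95% range 5734 to 5943) when the peaks were placed at random on their arms, a ratio of 0.29 (permutation p = 0.002). With peaks under 1 kb apart merged, the ratio was 0.52 (permutation p = 0.002). Strong peaks were grouped as well, with a median distance of 42193 bp against 60011 bp for random placement (ratio 0.70, permutation p = 0.002). With random placement within 100 kb bins, also added later, that kept the number of peaks in each, the ratio was 0.50 (permutation p = 0.002).

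Long stretches of 2L and 3L held few weak peaks and few peaks of intermediate score, while strong peaks remained. The limits of both stretches were chosen after their values were seen. From 2 to 10 Mb on 2L there were 13.8 weak peaks per Mb, against 59.8 on the rest of the arm, whereas strong peaks stood at 9.50 and 9.22 per Mb. From 6 to 17 Mb on 3L there were 11.1 weak peaks per Mb against 66.5 on the rest, and 9.0 strong peaks per Mb against 11.5. Peaks of all scores stood at 38.5 per Mb in the stretch of 2L and 131 on the rest. On 3L these values were 36.3 and 132. With limits so chosen, 2L and 3L outside the stretches were no poorer in peaks than 3R as a whole (129 per Mb). In the stretch of 2L, 89.3% of peaks lay on the score ladder, against 39.2% on the rest of the arm. In that of 3L the values were 84.0% and 59.8%. The bin from 8 to 9 Mb of 3L was an exception, with 51.5% of its 66 peaks off the ladder and 25 weak peaks. Over the 116 complete bins of 1 Mb on the 5 long arms, weak peaks ranged from 2 to 145 per bin (median 59) and strong peaks from 0 to 26 (median 11). Beyond counting noise, the coefficient of variation across bins was 59.6% for weak and 34.9% for strong peaks. The counting noise taken off is that of independent peaks, so local grouping of peaks may add to both values.

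**Figure D3:**
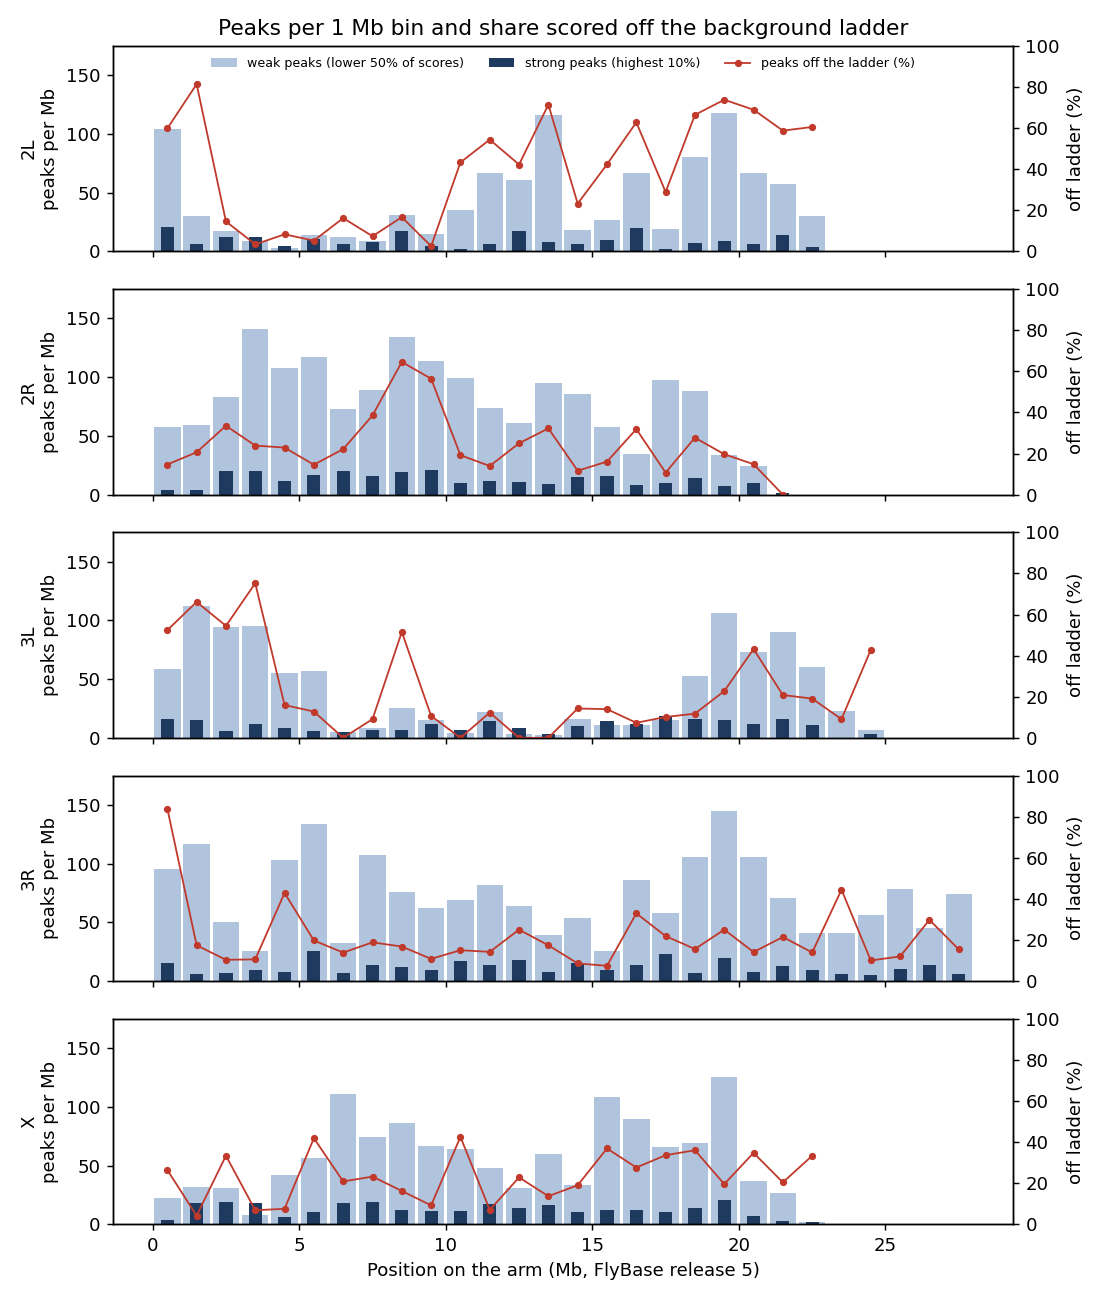
Weak peaks (lower 50% of scores, light bars) and strong peaks (highest 10%, dark bars, drawn from the same zero line) per 1 Mb bin along the 5 long arms, with the percentage of all peaks in the bin that lie off the score ladder (line, right axis). On 2L from 2 to 10 Mb and on 3L from 6 to 17 Mb the light bars are low while the dark bars persist.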

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

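The tests in this part were chosen after the result was seen. Peaks outside the chromosome arms, which enter none of the comparisons between arms, numbered 471 and are listed because they carry signal in sequence left out of the main measurement. They had a median score of 44.7, against 15.8 on the arms, and a median width of 418 bp, against 452 bp. Most lay on the unplaced sequences Uextra (270 peaks) and U (62 peaks), and 139 lay on the heterochromatic scaffolds. The highest was on 2RHet from 2842587 to 2845636, with a score of 1010.4 that only 2 peaks on the arms exceeded. The labels call the line female, and 1 peak lay on YHet, from 72043 to 73285, with a score of 257.79. This YHet peak and the highest 2RHet peak both lay off the ladder, so folds taken from their scores are upper bounds.

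A candidate explanation for the peaks on U and Uextra is that reads of repeated sequence gather there in the ChIP and the input alike. It requires that more of these peaks were scored against a raised local background than peaks of similar score on the arms. Off the ladder were 55.1% of the peaks on U and Uextra and 31.7% of those on the arms. The odds ratio within bands of 10% of the score was 2.72 (95% interval 2.18 to 3.40, two-sided permutation p = 0.0002, the smallest that 10000 permutations allow). The difference depended on the arm, however. Within the same bands the odds ratio was 2.26 to 3.93 against 3L, 2R, X and 3R taken singly. It was 1.31 (95% interval 1.02 to 1.68) against 2L, where 54.0% were off the ladder, and 0.99 (0.58 to 1.71) against arm 4, where 51.0% were. Not every arm was exceeded, and repeated sequence and binding of Su(H) there cannot be told apart, since no library's reads and no repeat annotation were used here. No biological explanation was tested, because the design has a single cell line and antibody.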

How the results depend on the processing

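The number of peaks was 7192 with the upper 50% of scores, by construction, and 6539 after peaks under 1 kb apart were merged. With the upper 50% of scores the ratio of peak share to length share rose to 0.97 on 2L, which ended its call (adjusted exact binomial p = 0.34), and turned to 0.99 on 3R (0.81). After merging, that of arm 4 turned to 1.04 (0.91). With the highest 10% of scores, a setting chosen after seeing the data, the ratios of 3L (0.91, adjusted p = 0.14 by the exact test) and 3R (1.04, adjusted p = 0.40) no longer passed the threshold. The cause was not tested. The deficits of 2L (0.82) and arm 4 (0.27, from 4 peaks) did pass with the highest 10%, each with adjusted exact binomial p = 0.0066. The excess on 2R passed under all 3 of these settings, with ratios of 1.15 to 1.29, and X missed the threshold under all 3. The ratio of X was 0.96 with the upper 50% and 1.00 after merging. With the highest 10% it was 1.12, just short of the threshold (adjusted exact binomial p = 0.0503). Each of these tests takes peaks as independent, and peaks per arm were not tested by exchanging windows. The share of strong peaks on each arm, a result chosen after seeing the data, was tested with whole windows of 100 kb exchanged among arms. With windows of 1 Mb in their place, 2R (8.47%, adjusted permutation p = 0.20), 3L (11.6%, 0.17), 4 (4.08%, 0.17) and X (11.4%, 0.20) no longer passed the threshold. With single peaks in place of windows, arm 4 did not pass (adjusted p = 0.089 by Fisher's exact test), and 2R, 3L and X did. The clustering ratio stayed below 1 under 5 alternatives, from 0.29 to 0.70 (0.52 after merging), of which placement within bins and the highest 10% were added later. The fitted background was 195.927 for all peaks, for peaks on the arms, and for odd-numbered and even-numbered peaks. Of the alternatives fixed in advance, 6 were run, and 20 were not because they need a genome or annotation of release 5. No paired analysis was possible because the list has no value per library, and leaving out a replicate was ruled out for the same reason.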

Other observations

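In this part, the test of weak peaks beside strong ones was set before its result was seen, and the tests on bins after. Peaks scored off the ladder were concentrated in some bins. On 3R they made up 84.0% of the 187 peaks in the first Mb, and on 2R 64.6% and 56.4% of the peaks from 8 to 9 and from 9 to 10 Mb. On 3L the share was 75.2% from 3 to 4 Mb. On 2L it was 81.4% from 1 to 2 Mb, a bin with 30 weak peaks, and 71.4% from 13 to 14 Mb, a bin with 116. It was low in other bins of 2L, with 2.56% of 39 peaks from 9 to 10 Mb and 8.33% of 12 peaks from 4 to 5 Mb.

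A hypothesis is that the number of weak peaks per Mb partly follows the local input level, which in a cell line may vary with DNA copy number. Where the input is at or below average, a caller that uses at least the genome-wide background needs a larger true enrichment to call a site. Over the 116 complete bins, the number of weak peaks and the share of upper-50% peaks off the ladder had a Spearman's rho of 0.43 (rotation of the bins within each arm, p = 0.0001, the smallest that 10000 rotations allow). This rests on 2L and 3L, the arms on which the pattern was first seen, with a rho of 0.83 and 0.86. Within 2R, X and 3R rho was 0.02, 0.06 and 0.20, and none passed the threshold, so the explanation stays open. Single arms have only 21 to 27 bins to rotate, so the smallest p possible within an arm lies close to the threshold. Even on 2L and 3L the rotation p was 0.043 and 0.040. The share of strong peaks also differed between bins (chi-square 510, permutation p = 0.0001). It was at most 268 when whole windows of 100 kb were exchanged among bins to keep groups of peaks together. This does not decide whether peak-rich bins hold more sites of every strength. The bins of 2L and 3L that raised the question are in the test. The classes also follow scores, whose background may differ between bins. Chromatin that holds more weak sites and also shears or recovers better in the input stays open, as does copy number itself, since no input reads were used here.

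Weak peaks also lay close to strong ones. Of 7133 weak peaks on the arms, 7.07% were within 1 kb of the edge of a strong peak, against 3.24% (95% range 2.83% to 3.66%) when placed at random within their own 100 kb bin outside stronger peaks. The test took wide enriched regions split by the caller to give an excess only within 1 kb of the edge. That limit was assumed. The list holds 125 peaks of 5 kb or more, so pieces of a split region may lie further out. At 1 to 5 kb the share was still 18.4% against 11.7% (11.0% to 12.4%), 1.57 times the placed share (permutation p = 0.002, the smallest possible). The test therefore does not decide on splitting. Random placement kept only the number of peaks in each 100 kb bin, and peaks of all classes are grouped within such bins. The excess is therefore not shown to be particular to strong peaks. At 5 to 20 kb the observed 30.5% lay within the placed range of 29.9% to 32.0%. Split wide regions, separate weaker sites around strong ones, or chromatin open over a few kb and recovered in any ChIP may all give this. A control antibody was not analysed here.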
